A study of Oryza sativa with 42 samples.

How the data were processed

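Leaf disks of 6 mm were cut from the uppermost leaf blades of 1-month-old rice plants and floated with 0.5 mM methyl jasmonate or with 0.1% dimethyl sulfoxide as control for 24 h, per the labels. RNA was extracted with a column kit, amplified and labelled with 1 dye, and hybridised to Agilent rice 4x44K arrays. Wild-type 'Nipponbare' and 2 lines each of oscoi1a, oscoi1b and oscoi2 were measured with both treatments on 3 arrays each, 42 arrays on 11 slides, all scanned on 1 day. How the mutations were made is not given in the sources used here.

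The deposited scanner files hold 1 signal intensity per spot for 45151 spots, extracted by the authors with Feature Extraction 10.5.1.1 and its protocol GE1_105_Dec08, per the file headers. The processed signal intensity used here is, per the file headers, background subtracted and detrended within an array, with no scaling between arrays. The deposited value table of the series holds log2 values for 42537 probes, and 99.8% of them lay within 0.05 log2 of the scanner signal scaled to the 75th percentile of each array after each probe was centred on its own level. Gene loci and descriptions came from the array annotation in the scanner files, and no locus matched the reference gene table at hand, so gene symbols were assigned by locus from textbook knowledge.

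Log2 processed signal was scaled to the 75th percentile of the 43734 noncontrol spots of each array, and spots flagged as outliers by the extraction software (23 to 107 per array) were left out. No noncontrol spot was saturated, 64.3% to 74.9% of spots per array were well above background, and the 75th percentile signal ran from 1136.7 to 2897.5. Replicate spots were averaged, and a probe was tested when it was well above background on all 3 arrays of at least 1 group (32840 of 42477 probes). Each locus was represented by its brightest tested probe, which left 22520 features, 22416 of them loci (called genes here). Arrays of the same group correlated at 0.982 to 0.997 across genes, which are not independent replicates.

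The tests were fixed before the data were examined. Limma 3.58.1 in R 4.3.3 fitted 14 group means with 28 residual degrees of freedom, and moderated the variances. The 13 contrasts were the response to MeJA in each of the 7 lines, the mean response of the 2 lines of each mutant minus the wild-type response, and the mean control level of the 2 lines minus the wild-type control. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called with an adjusted p under 0.05 and a change of at least 2-fold. Where a group was below background, the fold is given as a bound. It compares the mean of the brighter group over all replicates with the mean in the dimmer group of the higher of the lowest signal among probes well above background on that array and the probe's own signal. Data were also simulated with independent normal noise at the fitted spread of each gene, without slide effects or correlation between genes. There 94% of changes of 1.5 log2 were recovered in the wild-type response, 89% in the oscoi2 difference and 96% in the oscoi2 controls, and 1 unchanged gene was called in each.

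Gene lists fixed beforehand (33) covered jasmonate perception, synthesis, catabolism and transcription factors, defence metabolism and proteins, photosynthesis, ribosomes, hormones, growth, stress and markers of other tissues. The 26 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation. After the data were seen, 8 lists were also run without members whose description names another kind of protein, adjusted over these 8. List counts adjusted over the list alone use only the members' p-values. Genes are named by a rule fixed beforehand. It takes per contrast the 10 called genes that rose and the 10 that fell most with arrays that did not overlap and a described function, up to 4 called members per list, and in every line the COI, JAZ, jasmonate synthesis, transcription factor and marker genes. Genes of JAZ14 and JAZ15 had no probe under the locus looked for and were not analysed here.

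Alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited value table, no filter on dim probes, only probes above background on all arrays and the mean over probes. Others were slide or replicate number as a block, leaving out 1 array, only the groups of a contrast, moderation with a trend, the adjusted p alone and limma's test against a 1.5-fold change. Slide blocks used statmod 1.5.0. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, tables handled with data.table in version 1.17.8 and figures drawn with matplotlib 3.10.9.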

Results

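Leaf disks of rice were treated for 24 h with 0.5 mM methyl jasmonate (MeJA) or its solvent, in wild-type 'Nipponbare' and in mutants of the receptor genes COI1a, COI1b and COI2, each mutant represented by 2 lines. COI proteins are F-box proteins that perceive jasmonoyl-isoleucine together with JAZ repressors, which they mark for degradation. Each of the 14 combinations of line and treatment was hybridised to 3 one-colour arrays, 42 arrays in all. Values below are log2 differences with the standard error from limma, 3 arrays per group unless stated, and a gene was called when its limma adjusted p was under 0.05 and its change at least 2-fold. The p-values measure only the spread between these samples, since the labels name biological replicates without saying whether each came from separate plants.

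The targeted transcript was lower in both lines of each mutant. In control disks the log2 level of COI1a was 1.82 ± 0.05 (mean ± SD, n = 3 arrays) in wild type, -0.41 ± 0.17 in oscoi1a #1 and -0.53 ± 0.07 in oscoi1a #2. COI1b was at 2.47 ± 0.06 in wild type, 1.07 ± 0.08 in oscoi1b #2 and 1.19 ± 0.10 in oscoi1b #3, and COI2 at 0.97 ± 0.07, -0.49 ± 0.03 in oscoi2 #1 and -0.06 ± 0.03 in oscoi2 #2. With both lines averaged, the differences from wild type were -2.29 ± 0.07 for COI1a (limma adjusted p = 3.02e-21), -1.34 ± 0.07 for COI1b (limma adjusted p = 1.43e-15) and -1.24 ± 0.07 for COI2 (limma adjusted p = 1.77e-14). The 2 other COI transcripts of each mutant lay between -0.14 and 0.15 log2 of wild type and were not called. Across all loci, COI1a in oscoi1a, COI1b in oscoi1b and COI2 in oscoi2 were the only ones whose level in both lines of a mutant was more than 2-fold below every other line with and without MeJA (1 locus per mutant). By the same rule 5 loci in oscoi1a and 8 in oscoi2 were above every other line. MeJA called none of the 3 COI transcripts in any line, and the difference for COI1b was -0.55 ± 0.08 in wild type.

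**Figure D1:**
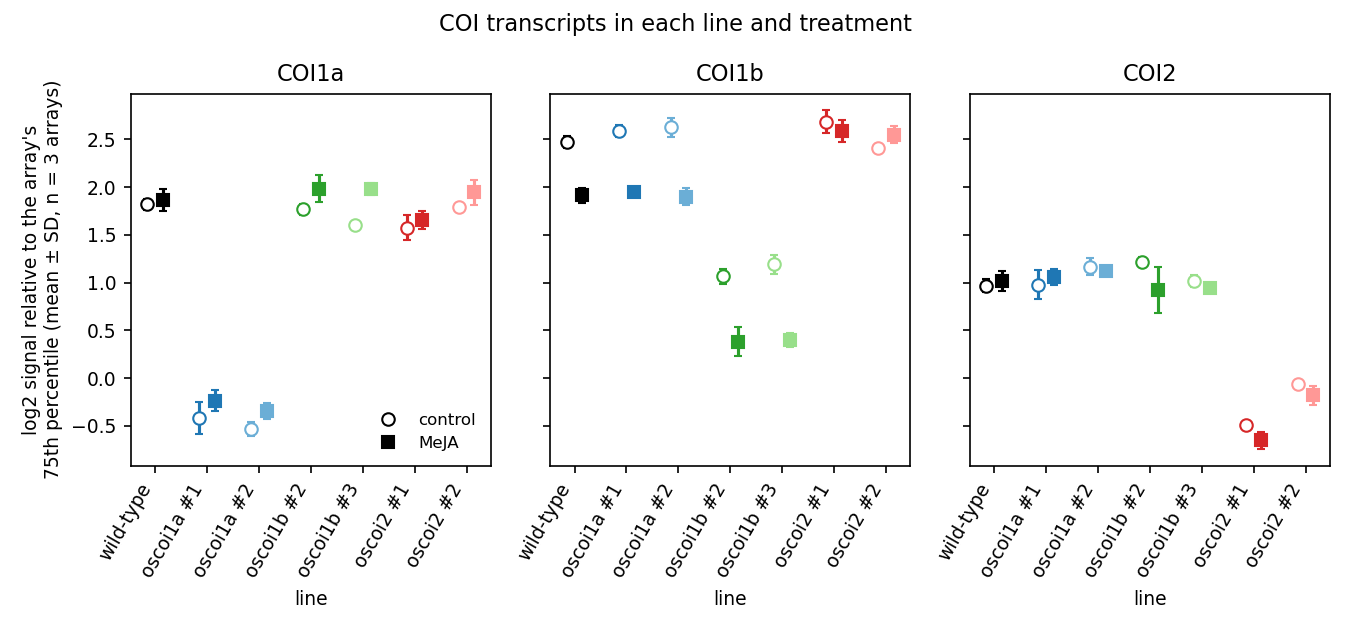
Log2 signal of COI1a, COI1b and COI2 relative to the 75th percentile of each array (vertical axis) in the 7 lines (horizontal axis), control as open circles and MeJA as filled squares, mean ± SD of 3 arrays. Each transcript is lower in both lines of its own mutant, with log2 differences of -2.29 for COI1a, -1.34 for COI1b and -1.24 for COI2 in control disks.

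MeJA raised the transcripts of the jasmonate pathway itself in wild-type disks. Of 13 JAZ repressor genes tested, 11 rose and 0 fell (11 and 0 adjusted over the list alone). JAZ9 was higher by 6.32 ± 0.23, JAZ5 by 4.79 ± 0.19, JAZ10 by 4.33 ± 0.17 and JAZ13 by 4.33 ± 0.21. JAZ3 (0.38 ± 0.09, called with the mean over its probes) and JAZ4 (0.39 ± 0.08) were not called, since they changed less than 2-fold. Of 27 genes of jasmonate biosynthesis 15 rose and 3 fell (the same adjusted over the list alone). They included AOS1 (3.79 ± 0.15) and AOS2 (2.30 ± 0.14), the allene oxide synthases, AOC, the cyclase of the next step (1.28 ± 0.09), the reductase OPR7 (1.51 ± 0.06) and the lipoxygenase Os12g0559200 (6.09 ± 0.20). CYP94C2b, which oxidises jasmonoyl-isoleucine, rose by 5.30 ± 0.28 and was above background on 1 of its 3 control arrays. Among jasmonate transcription factors, MYC2 rose by 1.42 ± 0.13 and bHLH148 by 2.38 ± 0.27, while RERJ1 was below background in both wild-type groups. The JAZ list moved up against all other genes (camera adjusted p = 1.53e-06), as did jasmonate biosynthesis (adjusted p = 0.000861, and adjusted p = 0.0805 with an estimated correlation).

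Defence genes moved in both directions, with large increases at some. NOMT, the methyltransferase that makes the flavonoid phytoalexin sakuranetin, was higher by 5.10 ± 0.21, and the chalcone synthase Os07g0526400 by 5.78 ± 0.37. Of 59 phenylpropanoid and flavonoid genes 22 rose and 10 fell (the same adjusted over the list alone, camera adjusted p = 0.00728, and adjusted p = 0.292 with an estimated correlation). Of 12 genes of diterpenoid phytoalexin synthesis 7 rose and 2 fell (7 and 2 adjusted over the list alone), among them KSL10 (5.89 ± 0.25) and CPS4 (3.14 ± 0.23), and the list did not pass (adjusted p = 0.0816). The linalool synthase Os02g0121700 rose at least 37.7-fold from below background, PR1a by 5.97 ± 0.37, the wound-induced protease inhibitor WIP1 (Os01g0131900) by 4.80 ± 0.24 and the glutathione S-transferase Os03g0785900 by 6.52 ± 0.21. Of 51 glutathione S-transferase genes 21 rose and 14 fell (21 and 14 adjusted over the list alone, adjusted p = 0.0309, and adjusted p = 0.300 with an estimated correlation). Of 125 pathogenesis-related genes 40 rose and 21 fell (the same adjusted over the list alone, adjusted p = 0.0605). With its members checked by name, done after the data were seen, 33 of 101 rose and 18 fell (the same adjusted over the list alone, adjusted p = 0.0250 over the lists so checked, and adjusted p = 0.392 with an estimated correlation). The largest increases began near background, with signal above it on 1 of 3 control arrays. They were in the terpene synthase Os04g0344100 (10.87 ± 0.80), the acyl-carrier protein desaturase Os01g0880800 (10.41 ± 0.78) and the respiratory burst oxidase Os12g0541300 (10.39 ± 0.73).

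Genes of photosynthesis and of the plastid ribosome fell more often than they rose. Of 65 genes of the light reactions 47 fell and 8 rose in wild type (47 and 8 adjusted over the list alone). With its members checked by name, after the data were seen, 40 of 46 fell and 2 rose (the same adjusted over the list alone, adjusted p = 8.28e-13 over the lists so checked, and adjusted p = 0.118 with an estimated correlation). Changes were -8.13 ± 0.31 for the photosystem I subunit Os09g0481200, -7.77 ± 0.33 for the oxygen-evolving enhancer Os01g0501800 and -8.38 ± 0.58 for the chlorophyll-binding protein Os02g0197600. Of 24 carbon fixation genes 13 fell and 1 rose (13 and 1 adjusted over the list alone). The Rubisco small subunit Os12g0274700 fell at least 986-fold to below background, and the changes were -9.31 ± 0.46 for phosphoribulokinase Os02g0698000 and -8.05 ± 0.24 for sedoheptulose bisphosphatase Os04g0234600. Of 48 plastid ribosomal protein genes 27 fell and 0 rose (27 and 0 adjusted over the list alone), with a list median of -1.98, led by S5 (Os03g0452300, -4.47 ± 0.09) and L29 (Os02g0754300, -4.22 ± 0.07). Of the 245 cytosolic ribosomal protein genes 8 rose and 14 fell (the same adjusted over the list alone), and the list median was 0.25. By camera the plastid ribosome list passed (adjusted p = 2.87e-07) and kept its call with an estimated correlation. The light reactions (adjusted p = 9.05e-08, and adjusted p = 0.240 with an estimated correlation) and carbon fixation (adjusted p = 0.00728, and adjusted p = 0.244 with an estimated correlation) did not keep theirs. Nor did the cytosolic ribosome, which moved up (adjusted p = 7.62e-05, and adjusted p = 0.362 with an estimated correlation).

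In all, 7830 of 22520 genes were called in wild type, 3179 higher and 4651 lower. Over all genes tested, the 3 control and 3 MeJA arrays did not overlap for 77.9%, against a chance share of 10%. With slide as a fixed block the count was 7930, and on slide 1 alone, which held 3 control and 1 MeJA array, the list medians were 2.78 for JAZ, -2.66 for the light reactions and -1.90 for the plastid ribosome. With normexp background correction, which draws dim signals together, 4414 genes were called, and with probes above background on every array 4754.

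Both lines of oscoi1a and of oscoi1b responded to MeJA about as widely as wild type. The counts were 3318 higher and 4553 lower in oscoi1a #1, 3431 and 4879 in oscoi1a #2, 3472 and 4775 in oscoi1b #2, and 3582 and 4869 in oscoi1b #3. With slide as a fixed block they were 7782, 8104, 8132 and 8311 in all. Over the 3179 genes raised in wild type, with a median of 1.94 there, the medians were 1.85, 1.97, 2.05 and 2.04. Over the 4651 lowered genes, at -1.80 in wild type, they were -1.65, -1.76, -1.82 and -1.86. JAZ5 rose by 6.83 ± 0.19, 6.37 ± 0.19, 5.81 ± 0.19 and 6.59 ± 0.19 in these lines. AOS1 rose by 5.40 ± 0.15, 4.12 ± 0.15, 4.13 ± 0.15 and 4.39 ± 0.15, and NOMT by 5.20 ± 0.21, 5.02 ± 0.21, 5.15 ± 0.21 and 5.66 ± 0.21. The plastid ribosome list fell in each, with medians of -1.93, -2.00, -1.94 and -2.00 (camera adjusted p = 1.55e-07, 1.97e-08, 1.46e-06 and 4.87e-07), and on single slides the medians were -1.91, -2.04, -1.97 and -1.96.

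**Figure D2:**
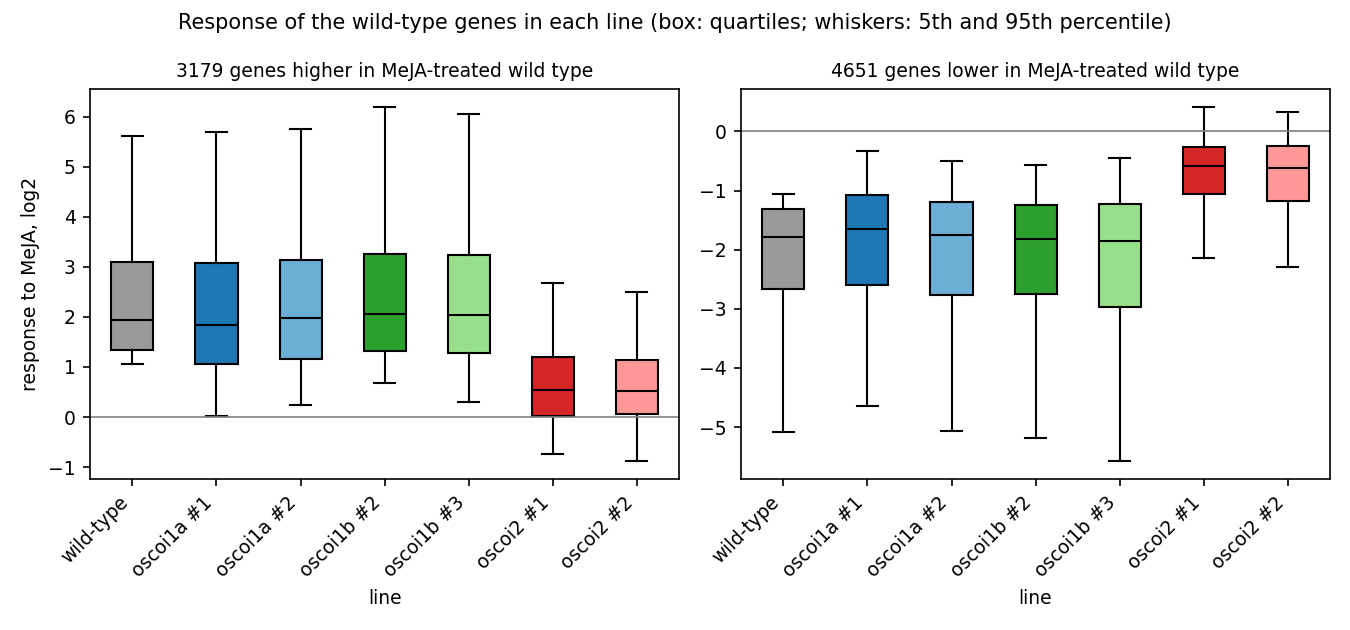
Response to MeJA in log2 (vertical axis) in the 7 lines (horizontal axis) of the 3179 genes raised and the 4651 genes lowered in wild type, with boxes for quartiles, a bar for the median and whiskers for the 5th and 95th percentile of genes. Medians of raised genes are 0.54 in oscoi2 #1 and 0.53 in oscoi2 #2, against 1.85 to 2.05 in the oscoi1a and oscoi1b lines.

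The oscoi1a response differed from the wild-type response at named genes in both directions. The lipoxygenase Os12g0559200 rose by 3.59 ± 0.20 and 3.21 ± 0.20 in the 2 lines (difference from wild type -2.69 ± 0.25). The transcription factor gene DREB1A Os09g0522200, of a family that binds cold and drought response elements, rose by 5.80 ± 0.23 in wild type. In oscoi1a it rose by 1.20 ± 0.23 and 1.00 ± 0.23, calls that were lost with slide as a fixed block (difference from wild type -4.70 ± 0.29). The DnaJ protein gene Os06g0716100, raised by 3.12 ± 0.22 in wild type, differed by -4.19 ± 0.27, and the P450 Os02g0703600 by -4.11 ± 0.21. PR1b rose more, by 7.45 ± 0.31 and 4.38 ± 0.31 against 2.17 ± 0.31 in wild type (difference 3.75 ± 0.38, limma adjusted p = 3.24e-09), as did JAZ5 (difference 1.81 ± 0.24). Of 79 cell division genes 13 responded more positively and 0 less (13 and 0 adjusted over the list alone, camera adjusted p = 5.33e-06, and adjusted p = 0.119 with an estimated correlation). Examples are histone H2A Os08g0427700 (2.37 ± 0.31) and the kinesin Os04g0629700 (1.76 ± 0.17). Part of these differences lay in the control disks, and levels after MeJA were compared with wild type once this was seen. PR1b, at -4.19 ± 0.27 in oscoi1a controls, was at -0.44 ± 0.27 after MeJA, and the lipoxygenase, at 2.93 ± 0.18, was at 0.23 ± 0.18. JAZ5 (0.25 ± 0.17), histone H2A Os08g0427700 (0.58 ± 0.22) and the kinesin Os04g0629700 (0.54 ± 0.12) were not called after MeJA either. Of the 79 cell division genes 4 were higher and 0 lower after MeJA (the same adjusted over the list alone, adjusted p = 1.66e-06, and adjusted p = 0.117 with an estimated correlation). DREB1A Os09g0522200 (-3.10 ± 0.20), the DnaJ gene Os06g0716100 (-1.90 ± 0.19) and the P450 Os02g0703600 (-2.05 ± 0.15) were lower after MeJA. In all 2273 genes were called, 1187 more positive and 1086 less. Of these, 380 and 228 were called the other way in the controls, and 1367 of the 2273 were called with the same sign in each line. With slide as a fixed block 2710 were called, with oscoi1a #2 alone 2252, and with normexp 906.

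PR1b and diterpenoid phytoalexin genes rose more in oscoi1b than in wild type, but from lower control levels. PR1b rose by 5.88 ± 0.31 and 5.89 ± 0.31 (difference from wild type 3.72 ± 0.38, limma adjusted p = 8.54e-09), was at -4.12 ± 0.27 in the controls and at -0.40 ± 0.27, not called, after MeJA. Of 12 diterpenoid phytoalexin genes 8 responded more positively and 0 less (9 and 0 adjusted over the list alone, camera adjusted p = 9.93e-07, and adjusted p = 0.285 with an estimated correlation). Among them CYP99A3 differed by 3.31 ± 0.31, KSL7 by 3.33 ± 0.66 and CPS4 by 1.49 ± 0.28, of which KSL7 and CPS4 lost their call on arrays of single slides. After MeJA these 3 stood at 0.81 ± 0.22, 0.48 ± 0.46 and 0.06 ± 0.20 from wild type and were not called, and of the 12 genes 1 was higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.469). The metallothionein Os12g0571100 fell in wild type (-6.48 ± 0.41) and oscoi1b #2 (-1.68 ± 0.41) and rose by 4.62 ± 0.41 in oscoi1b #3 (difference from wild type 7.94 ± 0.50). Its level in the oscoi1b controls was far below that in the wild-type controls, as given below, so much of this difference lay in the controls. DREB1A Os09g0522200 rose by 2.64 ± 0.23 in oscoi1b #2 and stood at -0.73 ± 0.23 in oscoi1b #3 (difference -4.84 ± 0.29), and the wound-induced protein Os04g0635500 differed by -3.81 ± 0.23. Of 79 cell division genes 8 responded more positively and 0 less (8 and 0 adjusted over the list alone, adjusted p = 0.00200, and adjusted p = 0.285 with an estimated correlation). After MeJA 7 of them were higher than in wild type and 0 lower (the same adjusted over the list alone, adjusted p = 6.83e-06, and adjusted p = 0.128 with an estimated correlation). In all 1328 genes were called, 714 more positive and 614 less, of which 348 and 170 were called the other way in the controls. Of the 1328, 592 had the same sign in each line, and the count was 1494 with slide as a fixed block. The p-values measure the spread between arrays of a group and not that between lines. The 2 oscoi1b lines differed from each other in their response at 1608 genes. Taken singly, oscoi1b #2 differed from wild type at 1192 genes and oscoi1b #3 at 2085, while the 1328 rest on the mean of both lines. For that mean, 675 were called with normexp, and 727 with limma's test against a 1.5-fold change.

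**Figure D3:**
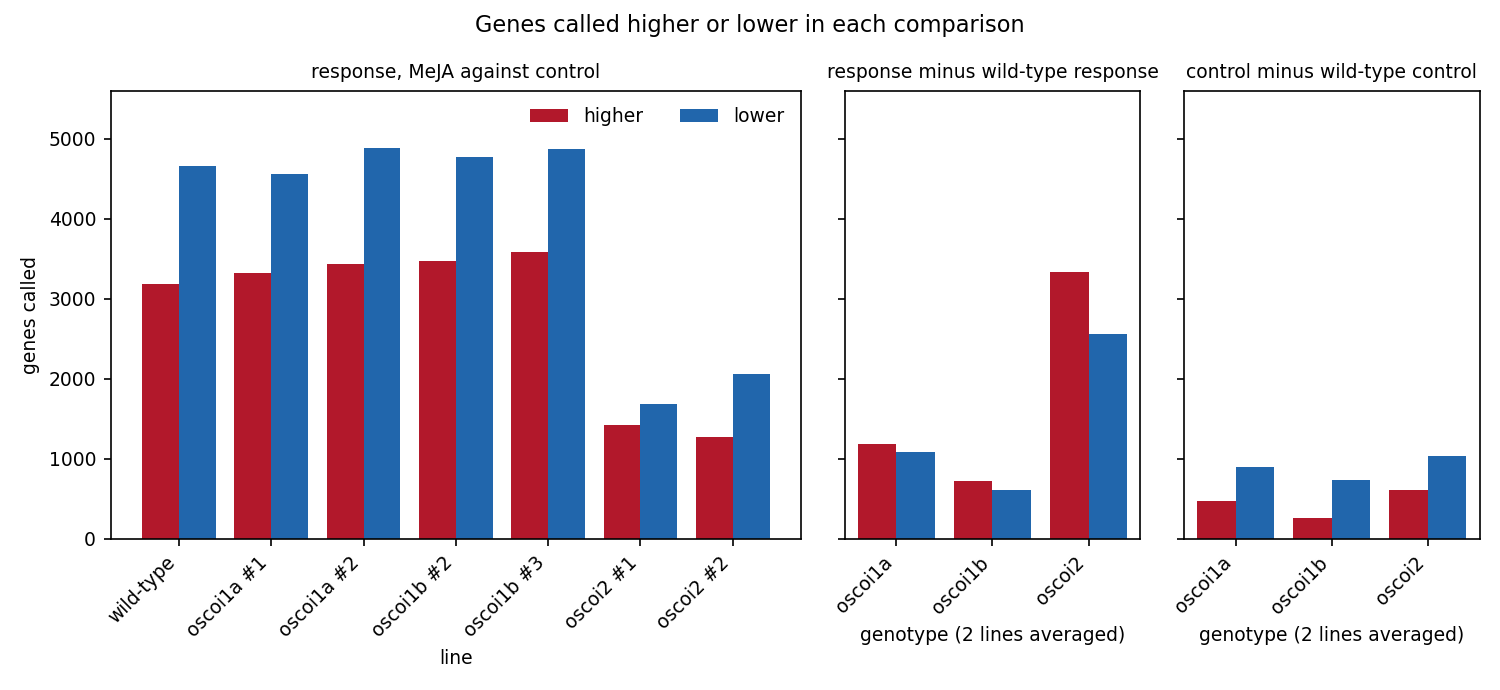
Number of genes called higher or lower (vertical axis) in each line's response to MeJA, in each genotype's response minus the wild-type response, and in each genotype's control minus the wild-type control (horizontal axis). The oscoi2 lines have 3091 and 3326 called genes against 7830 in wild type, and the response of oscoi2 differs from wild type at 5897.

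Both oscoi2 lines kept a response to MeJA that was smaller at most of the genes that moved in wild type. JAZ9 rose by 3.01 ± 0.23 in oscoi2 #1 (above background on 2 of 3 control arrays) and 2.84 ± 0.23 in oscoi2 #2 (difference from wild type -3.39 ± 0.28, limma adjusted p = 5.30e-12). AOS1 rose by 1.62 ± 0.15 and 1.66 ± 0.15 (difference -2.15 ± 0.19), and NOMT by 1.92 ± 0.21 and 1.80 ± 0.21 (difference -3.24 ± 0.26, limma adjusted p = 3.06e-12). The lipoxygenase Os12g0559200, at 0.17 ± 0.20 and 0.35 ± 0.20, and AOS2, at 0.07 ± 0.14 and 0.10 ± 0.14, were not called. The lipoxygenase was already higher in the oscoi2 controls than in wild type, as given below, so part of its smaller response lay in the controls. Of 13 JAZ genes 8 rose in oscoi2 #1 and 6 in oscoi2 #2, with 0 that fell (8, 6 and 0 adjusted over the list alone), and the list moved up in both (camera adjusted p = 2.81e-07 and 6.15e-06). Against wild type 8 JAZ genes responded less and 0 more (the same adjusted over the list alone, adjusted p = 0.000136, and adjusted p = 0.0638 with an estimated correlation). Of 27 biosynthesis genes 12 had a less positive response and 3 a more positive one (both counts the same adjusted over the list alone, adjusted p = 0.000299, and adjusted p = 0.0504 with an estimated correlation).

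**Figure D4:**
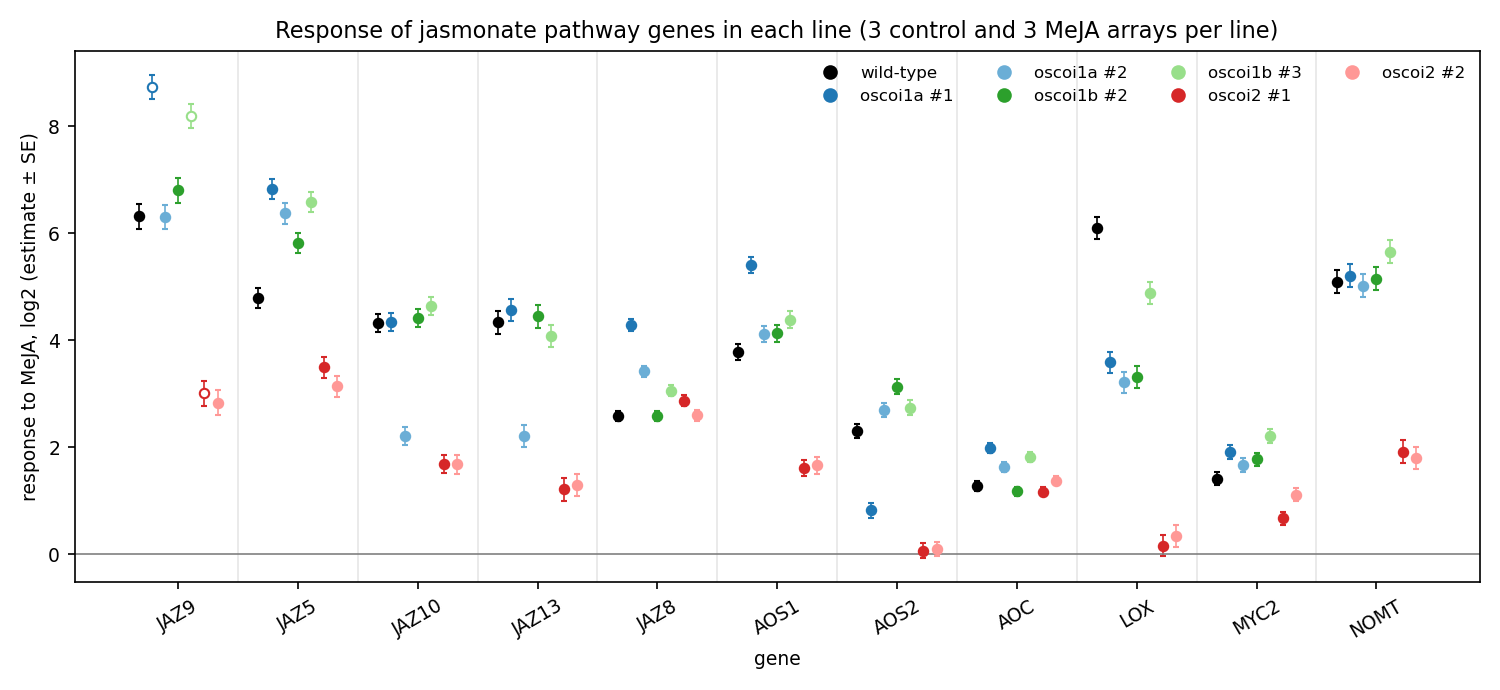
Response to MeJA in log2, estimate ± SE from 3 control and 3 MeJA arrays (vertical axis), of 11 jasmonate pathway and marker genes (horizontal axis) in the 7 lines, where open circles mark a group that was below background on at least 1 array. JAZ9, AOS1 and NOMT lie lowest in both oscoi2 lines, at 1.62 to 3.01, while JAZ8 (2.88 and 2.60) lies within the range of the other lines (2.58 to 4.28).

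Many photosynthesis genes fell less in oscoi2. The Rubisco small subunit Os12g0274700 changed by -2.51 ± 0.55 and -2.72 ± 0.55 in the 2 lines, against the fall to below background in wild type. The change was in sedoheptulose bisphosphatase Os04g0234600 -1.51 ± 0.24 and -1.57 ± 0.24 (difference 6.51 ± 0.30), and in the oxygen-evolving enhancer Os01g0501800 -1.46 ± 0.33 and -1.32 ± 0.33 (difference 6.38 ± 0.40). Against wild type 38 of 65 light reaction genes had a more positive response and 5 a less positive one (38 and 5 adjusted over the list alone, camera adjusted p = 3.03e-07, and adjusted p = 0.237 with an estimated correlation). With members checked by name, after the data were seen, 34 of 46 had a more positive response and 2 a less positive one (the same adjusted over the list alone, camera adjusted p = 3.33e-11 over the lists so checked, and adjusted p = 0.192 with an estimated correlation). Of 48 plastid ribosome genes 24 had a more positive response and 0 a less positive one (24 and 0 adjusted over the list alone, adjusted p = 4.28e-07, a call kept with an estimated correlation). The fall itself remained: 20 plastid ribosome genes fell and 0 rose in each line (the same adjusted over the list alone, adjusted p = 2.81e-07 and 2.90e-07), with medians of -0.91 and -0.79, and of -0.79 and -0.76 on single slides.

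Part of the response was not called weaker: 515 of the raised and 594 of the lowered wild-type genes were called in oscoi2 too, with no called loss. JAZ8 rose by 2.88 ± 0.10 and 2.60 ± 0.10 (difference from wild type 0.15 ± 0.12) and AOC by 1.17 ± 0.09 and 1.38 ± 0.09 (difference -0.00 ± 0.11). The P450 Os07g0419100 rose by 6.23 ± 0.17 and 6.44 ± 0.17, and by 5.20 ± 0.17 in wild type. The beta-primeverosidase Os09g0491100 rose by 6.76 ± 0.30 (above background on 1 of 3 control arrays) and 6.21 ± 0.30 against 1.81 ± 0.30 in wild type (difference 4.68 ± 0.37), where its call was lost with slide as a fixed block. Of 51 glutathione S-transferase genes 19 rose and 4 fell in oscoi2 #1 and 21 rose and 3 fell in oscoi2 #2 (the same adjusted over the list alone, camera adjusted p = 3.36e-06 and 7.00e-05, and adjusted p = 0.0522 and 0.126 with an estimated correlation). In the difference from wild type 14 were higher and 9 lower (14 and 10 adjusted over the list alone, adjusted p = 0.864).

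A smaller group moved the opposite way. DREB1A Os08g0545500, raised by 6.58 ± 0.25 in wild type, fell in both oscoi2 lines (-1.78 ± 0.25 and -1.75 ± 0.25, difference from wild type -8.35 ± 0.31). The expansin Os10g0542400, of a family that loosens cell walls, rose by 6.54 ± 0.21 in wild type and fell here (-1.52 ± 0.21 and -1.41 ± 0.21). The calls of both genes in oscoi2 #2 were lost under normexp. The acid phosphatase Os05g0189900 changed by -5.04 ± 0.37 in wild type (above background on 1 of 3 MeJA arrays) and rose by 3.74 ± 0.37 and 3.10 ± 0.37 in oscoi2. Of the genes called in wild type, 89 raised and 48 lowered ones were called in the opposite direction in oscoi2.

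In all 3091 genes were called in oscoi2 #1 (1414 higher, 1677 lower) and 3326 in oscoi2 #2 (1266 and 2060), or 2680 and 2964 with slide as a fixed block. Over all genes tested, the arrays of control and MeJA did not overlap for 63.3% and 57.8%, against a chance share of 10%. The response was called weaker than in wild type for 2058 of the 3179 raised genes (64.7%) and 2913 of the 4651 lowered ones (62.6%). For oscoi1a these were 582 and 475, and for oscoi1b 250 and 208. Called stronger were 23 raised and 29 lowered genes in oscoi2, 362 and 170 in oscoi1a and 278 and 170 in oscoi1b. The genes were chosen on the wild-type arrays that enter the difference, which favours weaker calls. The oscoi2 and wild-type responses differed at 5897 genes, 4934 of them with the same sign in each line, and at 5921 with slide as a fixed block. Of the 3335 more positive and 2562 less positive ones, 244 and 266 were called the other way in the controls. With normexp the counts were 1597, 1619 and, for the difference, 2578.

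**Figure D5:**
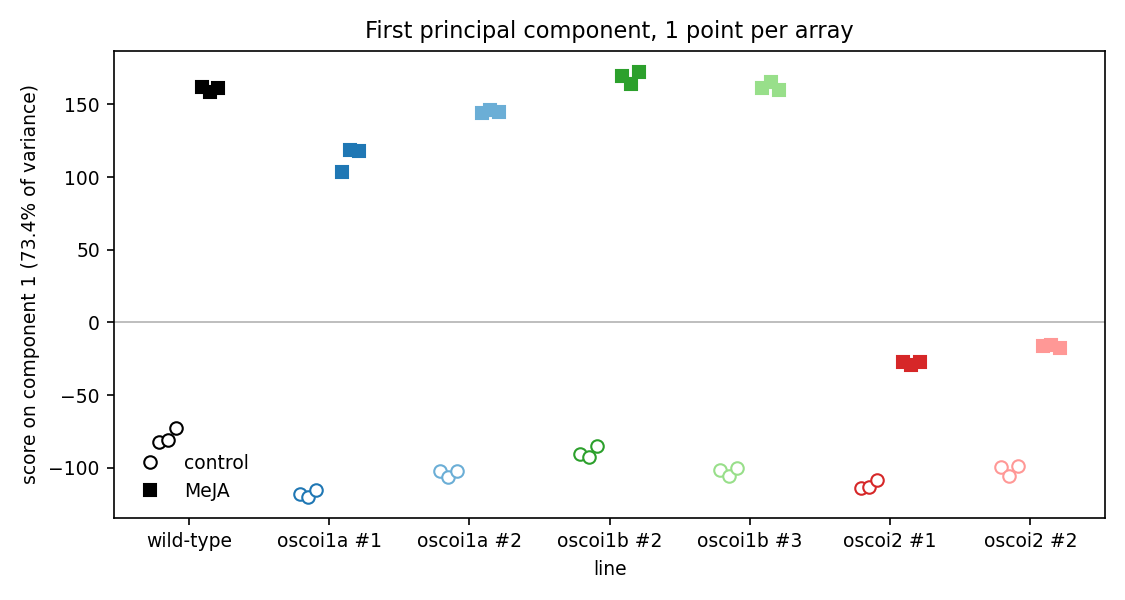
Score of each of the 42 arrays on the first principal component (vertical axis, 73.4% of the variance) by line (horizontal axis), control as open circles and MeJA as filled squares. MeJA arrays of oscoi2 lie at -29.4 to -15.4, between all control arrays (-119.8 to -72.9) and the MeJA arrays of the other lines (103.5 to 172.3).

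Without MeJA, diterpenoid phytoalexin genes were lower in all 3 mutants than in wild type. Of 12 tested, 9 were lower in oscoi1a, 9 in oscoi1b and 8 in oscoi2, with 0 higher (the same adjusted over the list alone, camera adjusted p = 4.15e-08, 2.31e-07 and 0.00229, and adjusted p = 0.120, 0.239 and 0.459 with an estimated correlation). After MeJA 8 were lower in oscoi1a and 10 in oscoi2, with 0 higher (the same adjusted over the list alone, adjusted p = 0.00136 and 0.00137, and adjusted p = 0.458 and 0.267 with an estimated correlation), and in oscoi1b 1 was lower and 1 higher. CYP99A3 differed by -2.30 ± 0.22, -2.50 ± 0.22 and -1.14 ± 0.22, and MAS, a momilactone synthase, by -3.09 ± 0.26, -2.03 ± 0.26 and -1.93 ± 0.26. KSL10 stood at -4.27 ± 0.22 in oscoi1a, where 3 of 6 arrays were above background, at -2.62 ± 0.22 in oscoi1b (5 of 6) and at -2.45 ± 0.22 in oscoi2. PR1b was lower too (-4.19 ± 0.27, -4.12 ± 0.27 and -1.75 ± 0.27). The differences were for the metallothionein Os12g0571100 -6.44 ± 0.36, -6.05 ± 0.36 and -6.55 ± 0.36, and for the chitinase gene Os04g0494100 -2.85 ± 0.24, -1.67 ± 0.24 and -1.62 ± 0.24. The lipoxygenase Os12g0559200 was higher by 2.93 ± 0.18, 1.12 ± 0.18 (a call lost under normexp) and 3.14 ± 0.18, and the DnaJ protein gene Os06g0716100 by 2.29 ± 0.19, 2.54 ± 0.19 and 2.09 ± 0.19.

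Some photosynthesis genes were higher in the oscoi1a controls. Of 65 light reaction genes 21 were higher and 2 lower (22 and 2 adjusted over the list alone, camera adjusted p = 1.06e-06, and adjusted p = 0.348 with an estimated correlation). Among them were CP24 (Os04g0457000, 2.69 ± 0.22) and CP29 (Os07g0558400, 2.85 ± 0.32), antenna proteins of photosystem II. Of 19 chlorophyll synthesis genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone, adjusted p = 0.00237, a call kept with an estimated correlation). They included the Mg-chelatase subunit Os07g0656500 (1.40 ± 0.18, not called with oscoi1a #2 alone). Plastid ribosome genes had a median of 0.31 with 0 called (adjusted p = 1.16e-05, a call kept with an estimated correlation). In oscoi2 CP24 was higher by 1.69 ± 0.22 (a call lost under normexp) and CP29 by 1.86 ± 0.32. There 8 light reaction genes were higher and 3 lower (the same adjusted over the list alone, adjusted p = 0.00670, and adjusted p = 0.613 with an estimated correlation). In oscoi1b 1 was higher and 2 lower (the same adjusted over the list alone, adjusted p = 0.657). With members checked by name, after the data were seen, 19 of 46 light reaction genes were higher and 0 lower in oscoi1a controls (camera adjusted p = 1.19e-11 over the lists so checked, and adjusted p = 0.437 with an estimated correlation). By that list 6 were higher and 1 lower in oscoi2 controls, and 0 higher and 1 lower in oscoi1b controls. These counts were the same adjusted over the list alone. Levels after MeJA, compared once the data were seen, were also higher in oscoi1a for 27 of the 65 light reaction genes and lower for 2 (the same adjusted over the list alone, camera adjusted p = 3.98e-09, and adjusted p = 0.219 with an estimated correlation). Of 24 carbon fixation genes 9 were higher there and 0 lower (the same adjusted over the list alone, adjusted p = 0.0137, and adjusted p = 0.402 with an estimated correlation). For levels after MeJA neither list was run with members checked by name.

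In all 1359 genes were called in the oscoi1a controls (465 higher, 894 lower), 990 in oscoi1b (255 and 735) and 1640 in oscoi2 (605 and 1035), and 487, 473 and 692 were lower in each line. Over all genes tested, the wild-type and mutant arrays did not overlap for 29.3%, 24.8% and 42.3%, against a chance share of 2.38%. The genes called in all 3 mutants were 102 higher and 435 lower, where independent lists would share 0.142 and 1.34 and unchanged simulated data gave at most 0. The simulated data held no difference between slides or lines, and independent lists would have no arrays in common. Neither value can therefore show how much of the sharing comes from the wild-type arrays. Part of that sharing may come from the 3 wild-type control arrays, which enter all 3 comparisons and all lie on slide 1, so that the slide and the line cannot be told apart here. This comparison depends on the scaling: under normexp the median of all genes moved by -0.36, -0.35 and -0.38. There 3094 genes were called in oscoi1b and 5531 in oscoi2, and the share of called genes that were higher went from 34.2% to 6.50%, from 25.8% to 1.65% and from 36.9% to 1.90%. Under quantile normalization that share was 38.0% in oscoi1b and 47.9% in oscoi2.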

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

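The counts of genes whose response differed and the fit with slide as a block were planned beforehand, but how the slide fit bears on the oscoi2 result was set afterwards. The other tests in this part were chosen after the results they bear on were seen, except that the prediction for slide 1 was written before its value was computed. By a test of the difference itself, the response to MeJA differed from wild type at 5897 genes in oscoi2, mostly as a loss. Exchanged control and MeJA arrays are excluded, since the oscoi2 MeJA arrays scored -29.4 or higher on the first principal component and the oscoi2 controls -98.9 or lower. Equal dilution of the treated disks by untreated tissue would take about the same log2 amount from each strongly raised gene. The test used 148 genes raised at least 16-fold in both oscoi1b lines and above background on every wild-type, oscoi1b and oscoi2 array. Their loss had a median of 2.67 log2, an interquartile range of 2.33 and a median standard error of 0.219, and 19 of them were not called weaker. This spread argues against equal dilution but does not exclude it. The standard error leaves out differences between lines, and the spread of these genes between oscoi1b and wild type was not computed. Slide is not the source, with 5921 genes once slide was a fixed block. A larger part for COI2 than for COI1a or COI1b in this response is 1 possible reading of these values. Only single mutants were measured, and how the mutations were made is not given, so the 3 genes cannot be ranked. Uptake of MeJA and the state of the tissue were not measured and remain open.

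Line oscoi1a #1 stood apart from all others, oscoi1a #2 included. It held 86 loci more than 4-fold below every other line with and without MeJA by measured signal, 54 of which were below background on all 6 arrays. With groups below background set to their bound, 57 of the 86 remained. Every other line had 0 or 1 such loci. It also held 24 loci above every other line, against 4 in oscoi1a #2 and 0 or 1 in the rest. Several of the 24, without a described match, had nearly the same levels and may not be separate signals. Os01g0129100 and Os04g0671600, for example, were at 2.83 and 2.87 in its controls and at 0.65 and 0.67 in wild type. Chosen after their values were seen, the phenylalanine ammonia-lyase genes Os12g0520200 and Os11g0708900 were at least 2179-fold and 397-fold below the nearest line in control disks. Dim arrays are excluded (69.9% of spots well above background on its dimmest array, against 64.3% on the dimmest of the others), and so are arrays of a line other than oscoi1a under this name, since COI1a was lower there too (-2.23 log2 from wild type), while an exchange between oscoi1a lines stays open. Chromosome segments that differ from the other lines fit: 24 of the low loci were on chromosome 7 and 26 on chromosome 12, and 46 of 86 had another among the 10 nearest tested loci on either side, against at most 21 in 10000 random sets (permutation p = 1e-04, the smallest possible), which may reflect a different background of that line, though no sequence was available to test it.

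Without MeJA, 435 genes were lower in all 3 mutants than in wild type, by a median of 1.65 log2. All 3 wild-type control arrays lay on slide 1 with 1 wild-type MeJA array, and over these genes that array lay 0.23 log2 above the wild-type MeJA arrays of slide 2. That is below the limit, a fixed part of that median, that was set beforehand as the sign of no slide effect, but it rests on 1 array, which excludes nothing, so slide and line cannot be told apart. A shared lowering of these transcripts by loss of any COI gene, a slide effect and a difference in how the wild-type plants were grown all remain possible explanations.

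Other results were flagged because 2 groups differed in the same contrast. The responses of oscoi1a and oscoi1b differed from wild type at 2273 and 1328 genes. The 2 lines of a mutant differed from each other in their response at 973 genes for oscoi1a, 1608 for oscoi1b and 252 for oscoi2. Some named genes rose in wild type and fell in a mutant, or the reverse, by a called difference. They were in oscoi2 DREB1A Os08g0545500 (-8.35), DREB1A Os09g0522200 (-8.22), the expansin Os10g0542400 (-8.01), the wound-induced protein Os04g0635500 (-6.32), the DnaJ protein Os06g0716100 (-4.79) and the acid phosphatase Os05g0189900 (8.46), in oscoi1a Os06g0716100 (-4.19), and in oscoi1b the metallothionein Os12g0571100 (7.94). The last rose in oscoi1b #3 alone and fell in oscoi1b #2. The controls of these mutants differed from wild type the other way at the metallothionein and at Os06g0716100, so part of these differences lay in the controls.

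The arrays were regrouped to ask whether any grouping of them gives such counts, over the 22391 genes with no missing value. Within a line, the real grouping gave 7790 genes in wild type, 7833 and 8265 in oscoi1a, 8201 and 8403 in oscoi1b and 3070 and 3309 in oscoi2, the highest of all splits (1 of 10 each). The highest others gave 21, 5, 3, 30, 4, 1 and 267, but 10 splits are too few to show a share under 0.05. For the differences from the wild-type response, 2 of 100 splits gave as many as the real 2262, 1321 and 5875, the highest others 2637, 1418 and 6671. For the controls 1 of 100 did, with 1346, 985 and 1632 genes and highest others of 1302, 669 and 1625. For these 6 counts the share of splits with as many genes was under 0.05. The splits moved single arrays, and arrays of a line are alike, so most splits break up the lines. They therefore cannot show whether another grouping of whole lines would give such counts. Most of the high other splits kept arrays of 1 group together: that of the oscoi1a controls, like that of oscoi2, held the 3 wild-type controls as 1 group and mixed only the 2 lines.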

How the results depend on the processing

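The 13 counts of called genes kept their size within 1.5 times under the deposited value table, quantile normalization, no filter on dim probes, the mean over probes, slide or replicate number as a block, moderation with a trend, and only the groups of a contrast. The settings chosen after seeing the data did so too: within slides, without the 2 oscoi2 #2 MeJA arrays of slide 11 (2948 genes in oscoi2 #2, 5768 for the oscoi2 difference) and with oscoi1a #2 alone (2252 and, for the controls, 1225). Below, counts run in the order wild type, oscoi1a #1 and #2, oscoi1b #2 and #3, oscoi2 #1 and #2, then the differences from the wild-type response and the controls, each for oscoi1a, oscoi1b and oscoi2. Under normexp 4414, 5099 (oscoi1a #2), 5261, 5396, 1597, 1619, 906, 675, 2578, 3094 (oscoi1b controls) and 5531 (oscoi2 controls) moved by more than 1.5 times, and the cause was not tested. With probes above background on all arrays, which tests fewer genes (16908), the counts were 4754, 4880, 5063, 5034, 5247, 1525, 1622, 1165, 643, 3446, 452, 288 and 612. With the adjusted p alone, which drops the limit on the size of change, they were 16838, 16909, 17057, 17025, 17044, 11599, 12699, 7954, 5349, 13928, 8539, 5871 and 10749. Against a 1.5-fold change the oscoi1b difference had 727 and the oscoi1b controls 608. Leaving out 1 array gave 7805 to 7891, 7794 to 7970, 8219 to 8364, 8172 to 8258, 8393 to 8472, 2987 to 3282, 3059 to 3738, 2127 to 2450, 1251 to 1403, 5805 to 6012, 1312 to 1421, 937 to 1055 and 1500 to 1757. With slide as a random block the controls had 1302, 927 and 1575 genes; a fixed block cannot be fitted for them. Replicate numbers did not pair samples (21 pairs, 0 with a correlation above 0.1), and with them as a block wild type had 7830. Normexp moved the median of all genes by -0.17 to 0.25 in the responses and by 0.15 to 0.21 in the differences. It moved the share of called genes that were higher from 41.3% to 53.1% in oscoi1a #2, 42.1% to 54.5% in oscoi1b #2, 38.1% to 50.5% in oscoi2 #2, 52.2% to 67.6% in the oscoi1a and 53.8% to 72.3% in the oscoi1b difference. Quantile normalization moved the median by 0.11 to 0.13 in wild type, oscoi1a and oscoi1b. Of 184 gene values printed, 0 reversed. Called or uncalled, 172 stayed so under normexp, 182 under quantile normalization, 145 of 150 with slide as a fixed block, and 1495 of 1506 in fits without 1 array. With an estimated correlation 20 of the called list results kept their call and 85 lost it. In the 8 lists run again with members checked by name, chosen after the data were seen, 24 called results kept their call, 1 lost it and 10 more were called. Of the 245 cytosolic ribosome genes 0 were called in the oscoi1a controls and 1, lower, in oscoi1b (both the same adjusted over the list alone). The list had moved down there (adjusted p = 0.0262 and 2.80e-06, and adjusted p = 0.802 and 0.630 with an estimated correlation) and moved up under normexp (adjusted p = 0.000131 and 0.00507), and the cause was not tested. A scan date block was not run, since all arrays share 1 scan day. Genes near background, such as those above it on 1 of 3 control arrays, have the least certain fold changes.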

Other observations

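Beyond the groups described above, MeJA changed genes of hormones and growth in wild type. Of 50 ethylene genes 16 rose and 9 fell (camera adjusted p = 0.0337, and adjusted p = 0.103 with an estimated correlation). The ACC synthase Os01g0192900, of the committed step of ethylene synthesis, rose by 6.26 ± 0.27 (above background on 2 of 3 control arrays), and the ACC oxidase Os09g0451000 changed by -7.17 ± 0.34. In oscoi2 16 ethylene genes responded less positively than in wild type and 6 more (adjusted p = 0.0130, and adjusted p = 0.0504 with an estimated correlation), and the ACC oxidase differed by 5.28 ± 0.41. Of 61 cell wall genes 18 rose and 7 fell (adjusted p = 0.0337, and adjusted p = 0.240 with an estimated correlation). Other lists did not pass in wild type. Growth and hormone lists were gibberellin (5 up, 2 down of 14, adjusted p = 0.485), auxin (7 and 18 of 61, 0.682), dehydration and abscisic acid (4 and 6 of 27, 0.823), starch and sucrose (8 and 19 of 50, 0.223) and cell division (7 and 13 of 79, 0.870). Stress and regulator lists were heat shock proteins (14 up, 27 down of 134, adjusted p = 0.325), WRKY factors (13 and 9 of 58, 0.180), bHLH factors (12 and 14 of 76, 0.823) and peroxidases (26 and 33 of 79, 0.870). The rest were protease inhibitors (15 up, 8 down of 36, adjusted p = 0.238), terpene synthases (10 and 3 of 22, 0.0718), chlorophyll synthesis (3 and 10 of 19, 0.0802), chlorophyll breakdown and senescence (2 and 4 of 16, 0.618) and reproductive tissue (3 and 11 of 33, 0.578). All counts were the same adjusted over the list alone. With members checked by name, done after the data were seen, 14 of 23 protease inhibitors rose and 3 fell (adjusted p = 0.00409 over the lists so checked, and adjusted p = 0.118 with an estimated correlation). In oscoi2 9 of these responded less positively than in wild type and 2 more (adjusted p = 0.0101, and adjusted p = 0.192 with an estimated correlation). Single members stood out: WRKY10 (Os01g0186000) rose by 4.22 ± 0.14, the gibberellin 2-oxidase Os05g0560900, which inactivates gibberellins, by 4.04 ± 0.30, and the peroxidase Os07g0677200 changed by -6.29 ± 0.30. Of the few marker genes of other tissues, the silicon transporter Lsi1 changed by -1.71 ± 0.18, PT2 by 1.33 ± 0.17, the sucrose transporter SUT1 by 1.13 ± 0.11 and the guard cell channel SLAC1 by -1.18 ± 0.11 (a call lost under quantile normalization). By contrast the meristem gene OSH15 rose at least 5.79-fold from below background.

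At the diterpenoid phytoalexin genes the 2 oscoi2 lines were compared after their values were seen. Of 12 genes, 8 responded more positively in oscoi2 #1 than in oscoi2 #2 and 0 less (9 and 0 adjusted over the list alone, camera adjusted p = 3.43e-10, and adjusted p = 0.161 with an estimated correlation). In the lines themselves 6 rose and 0 fell in oscoi2 #1 (adjusted p = 0.0305, and adjusted p = 0.441 with an estimated correlation), and 1 rose and 7 fell in oscoi2 #2 (adjusted p = 0.192). CPS4 stood at 0.92 ± 0.23 and -1.25 ± 0.23, MAS at 1.32 ± 0.30 and -1.36 ± 0.30, and CYP99A2 at 1.15 ± 0.40 and -2.42 ± 0.40, and with slide as a fixed block MAS and CYP99A2 lost their call in oscoi2 #1. KSL10 rose in both, by 3.12 ± 0.25 and 2.05 ± 0.25. On single slides the list medians were 0.40 and -1.46. Some genes kept a large fall in oscoi2: NEC1 (Os02g0513100) changed by -5.76 ± 0.50 and -6.45 ± 0.50 there and fell at least 111-fold in wild type. The water stress protein gene Os03g0316200 fell at least 35.3-fold in wild type and stood at 0.30 ± 0.23 and 0.36 ± 0.23 in oscoi2.

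The measured level of transcripts raised by MeJA differed between the wild-type control arrays, which also differed in brightness. Over 460 genes raised at least 16-fold in wild type, the median log2 level was -5.13, -5.23 and -4.35 on control arrays 1, 2 and 3, and 282, 243 and 315 of them were above background. Of all noncontrol spots, 74.8%, 68.9% and 72.3% were well above background on these arrays. The genes were chosen with these same arrays and many lie near background there. Controls of other lines were not compared over these genes, so the cause cannot be told. On the first principal component the wild-type controls lay at -82.2 to -72.9, nearer the MeJA arrays than the mutant controls (-119.8 to -85.3). All wild-type controls lay on slide 1, so slide and line cannot be told apart there either. Chosen after its values were seen, the ribonuclease P-related gene Os05g0270500 was at least 94.6-fold higher in the oscoi1a controls than in wild type, and the transporter gene Os04g0543600 at least 19.5-fold higher in the oscoi2 controls.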
